A study of Mus musculus with 28 samples.

How the data were processed

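The series holds 28 mouse samples, of which 20 are RNA-seq libraries and 8 are bisulfite or oxidative bisulfite sequencing libraries. RNA came from tumours grown from injected Hepa1-6 cells (4 WT and 4 KO hosts), from tumours grown from injected Py8119 cells (2 WT and 2 KO hosts), and from G-MDSC of the spleen of tumour-free mice (2 WT and 2 KO) and of tumour-bearing mice (2 WT and 2 KO). DNA came from G-MDSC of tumour-bearing mice, with 2 WT and 2 KO preparations that each gave a bisulfite and an oxidative bisulfite library. WT and KO are the genotypes for Tet2 as the labels give them, and the labels do not say which part of the gene was deleted. Per the labels' protocols, the RNA libraries were made with a TruSeq RNA kit, the oxidative bisulfite libraries with a TrueMethyl kit, the G-MDSC were taken with a magnetic isolation kit from Miltenyi, and tumours were ground and filtered.

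Per the submitters' processing notes, Trim Galore 0.4.4, TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff 2.2.1 and BSMAP (named with the versions 2.74 and 3.4.2) were used with the mouse genome build mm9, with no role or order given for any of them. The deposited RNA values are FPKM, calculated by the authors for each gene. Per the file headers, the RNA tables have the columns of a Cufflinks gene tracking table, and the annotation behind them is not stated. Whether the authors applied a scaling between libraries is not stated, and FPKM gives no read counts, so the sequencing depth of the RNA libraries is unknown. The deposited DNA values are a fraction between 0 and 1 for 5mC (5-methylcytosine) and another for 5hmC (5-hydroxymethylcytosine) at each CG cytosine and strand, given by the authors to 2 decimals. How the authors estimated 5hmC from a library pair is not stated. The deposited coverage signal is a whole number per cytosine of at least 20, is identical in the 5mC and the 5hmC file of a pair, and whether it counts reads of the bisulfite library, the oxidative library or the sum is not stated. For that reason no counting interval was computed for a cytosine.

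Rows of one gene symbol on one chromosome were summed, which gave 24001 genes, and estimates that Cufflinks marked as failed were left out. S100a9 and Ngp carried such marks in G-MDSC libraries and were therefore not tested there, and Tpm3, Ppp1r18, Ceacam1 and Actr3 were among the other genes left out. No pair of libraries held identical values, and the highest correlation between any 2 was 0.995. FPKM were scaled between libraries by median-of-ratios size factors, 1 was added, and log2 was taken. Genes with a mean scaled FPKM of at least 1 over the libraries of a fit were tested. The 12 tumour libraries were fitted together as 4 groups, and the 8 G-MDSC libraries as another 4 groups, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), so that each fit pooled the spread over its groups. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. A gene was said to rise, fall or change where it passed that threshold. The comparisons were KO against WT within each of the 4 settings, tumour-bearing against tumour-free within each genotype, and the difference of the KO effect between tumour lines and between tumour states.

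The 40 gene lists were fixed, together with the samples' groups, the tests and the alternatives, before the data were examined. They cover T-cell core, cytotoxic, NK cell, checkpoint, regulatory T cell, B-cell, plasma cell, dendritic, monocyte, macrophage, mature neutrophil, primary and secondary granule, suppressor-function (MDSC), granulocyte chemoattractant, inflammatory (NF-kB), IFN-γ response, type I interferon-stimulated, MHC class I, MHC class II, basophil-eosinophil-mast, erythroid, megakaryocyte, stem and progenitor, TET and DNMT, liver-secreted, mammary, keratinocyte, endothelial, fibroblast, muscle, adipocyte, proliferation, hypoxia, immediate-early, heat shock, oxidative phosphorylation, ribosomal, cholesterol synthesis and mitochondrially encoded genes. Lists with at least 5 members past the filter were tested with camera from limma against all other genes, at a preset correlation of 0.01, with p adjusted over the lists of a comparison. The same test with a correlation estimated from the libraries was run as an alternative. For each list the members were also counted with p adjusted over the list alone. Megakaryocyte lists (4 members past the filter in tumours, 2 in G-MDSC), the primary granule, muscle and adipocyte lists in tumours (4 each) and the NK cell (1 member) and endothelial lists (2 members) in G-MDSC were too small to test, and the mitochondrially encoded list had 0 members in the files.

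Genes were named by a fixed rule. Tet1, Tet2 and Tet3 were named throughout. Among genes past the threshold whose groups did not overlap and whose higher group averaged a scaled FPKM of at least 5, the 8 with the largest rise and the 8 with the largest fall were named, leaving out predicted genes and short RNA. Where fewer than 5 genes passed, the 5 rises and 5 falls with the smallest p were named and said not to pass. Up to 4 members of each described list were named by smallest p. For the DNA, up to 5 regions each way were named by size among those past the threshold, or up to 3 each way by smallest p where none passed.

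Cytosines with a coverage of at least 5 were kept, which removed none. Each sample's genome-wide level was the mean over its cytosines, compared by an exact permutation test of 2 against 2 samples, whose smallest possible p is 0.333. Region means used the 3935791 cytosines present in all 4 samples and regions with at least 10 of them, and were tested with limma as above. Gene bodies ran from the first to the last base of a gene in the RNA tables. The 245 genes whose rows lay at several separate loci of a chromosome gave no region, and all of their loci counted as genic. The reference held no strand, so the promoter was replaced by the 1000 bases on either side of the end of the gene that holds more CG cytosines, here called the gene end. Region levels are means of percentages, with the SD between samples.

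Replicate numbers were tested as pairs. The residuals of same-numbered G-MDSC libraries correlated at 0.495 to 0.724 over 12 pairs, so that their numbers 1 and 2 mark a pair of sets, and values within each set are given beside the group values of the main lists and of some genes. Same-numbered Hepa1-6 libraries correlated at -0.217 to 0.112, which does not pair them. The 2 pairs of Py8119 libraries correlated at 0.251, the same value mirrored. For DNA the same correlation was 0.0453 for gene-body 5hmC, 0.287 for gene-body 5mC, 0.0552 for gene-end 5hmC and 0.502 for gene-end 5mC. A fit with the replicate number as a block was run for every comparison. The labels do not say that the replicates came from separate animals, and if they did not, the p-values measure only the spread between these samples.

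The fits were tested on simulated data with 200 changed genes or regions. A first generator drew the noise of each gene or region from its own spread, and after its result was seen a second one drew variances from the prior that eBayes fitted. With the second generator, the Hepa1-6 comparison recovered 37.3% of genes changed by 0.5 on the log2 scale, 74.6% of those changed by 1 and 98.5% of those changed by 2, with 6 false calls among 146. The Py8119 comparison recovered 7.46%, 47.8% and 93.9%, and the difference between tumour lines 2.99%, 35.8% and 83.3%. The 5 G-MDSC comparisons recovered 0% of changes of 1, and 18.2% (tumour-free), 16.7% (tumour-bearing), 24.2% (WT tumour effect), 0% (KO tumour effect) and 0% (difference) of changes of 2. For gene-body 5mC, 0%, 2.99% and 65.2% of changes of 2, 5 and 10 percentage points were recovered, and for gene-body 5hmC 2.99%, 37.3% and 72.7%. For gene ends the same shares were 2.99%, 37.3% and 62.1% for 5mC and 0%, 25.4% and 45.5% for 5hmC. With the first generator, the Hepa1-6 comparison recovered 25.4%, 83.6% and 98.5% of changes of 0.5, 1 and 2, the Py8119 comparison 4.48%, 58.2% and 87.9%, and the difference between tumour lines 2.99%, 56.7% and 86.4%. For changes of 2 in G-MDSC it gave 25.8% (tumour-free), 51.5% (tumour-bearing), 56.1% (WT tumour effect), 28.8% (KO tumour effect) and 0% (difference). For changes of 1 it gave 1.49% in the tumour-bearing comparison, 4.48% for the WT tumour effect and 0% in the other 3. The gene-body tests recovered 0% at each size with the first generator, and the gene-end tests 5.97%, 43.3% and 65.2% for 5mC and 1.49%, 7.46% and 28.8% for 5hmC. With no list changed, camera called 0 lists in each comparison with the second generator, and with the first it called 1 in tumour-free G-MDSC and 0 in the others. The simulated noise was drawn for each gene on its own and held no correlation within lists. It could not show false calls from such correlation. Of the 35 splits of the 8 real Hepa1-6 libraries into 4 and 4, 20 gave at least the 15 lists of the real grouping. A raised list was called in each comparison with either generator. With the first, 1 other list was called with it in the Py8119 comparison and in the difference between tumour lines, and 2 others in tumour-free G-MDSC and for the WT tumour effect.

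The alternatives were a pseudocount of 0.1, no filter, a filter at 5, FPKM as deposited, quantile normalization, a robust eBayes, the replicate block, a fit of the 2 compared groups alone, the estimated correlation, coverage minimums of 3 and 10, at least 5 cytosines per region, 500 bases on either side of a gene end, weighting by coverage, cytosines present in all 4 samples, and leaving out each library in turn. Leaving out short RNA genes, leaving out 3 Hepa1-6 libraries together, a coverage minimum of 30, a coverage of 25 to 30 and autosomes alone were added after seeing the data. Scripts used Python 3.11.15, the R package data.table (version 1.17.8), numpy 2.4.6, pandas 2.3.3, pyarrow 21.0.0 and matplotlib 3.10.9.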

Results

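The data cover mice labelled WT or KO for Tet2, an enzyme that oxidizes 5mC to 5hmC. RNA was measured in Hepa1-6 liver cancer tumours (4 WT and 4 KO hosts) and in Py8119 mammary cancer tumours (2 and 2). It was also measured in spleen G-MDSC, neutrophil-like suppressor cells, of tumour-free (2 and 2) and tumour-bearing (2 and 2) mice. Each RNA library had 8083 to 11608 of 24001 genes at an FPKM of at least 1, and the sequencing depth is unknown because FPKM carry no counts. Base-resolution 5mC and 5hmC were measured in G-MDSC of tumour-bearing mice (2 WT and 2 KO). The samples held 11403417 and 12103828 cytosines in WT and 17822673 and 6869302 in KO, with a median coverage of 29 to 36. Short RNA genes made up 0.0805% to 1.95% of the FPKM sum in Hepa1-6 libraries, 98.2% to 99.3% in Py8119 libraries, 0.529% to 0.951% in the 1st G-MDSC set and 62.5% to 74.8% in the 2nd. The scaling between libraries was based on medians of ratios.

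Tet2 RNA was present in every group, and in none was it lower in KO than in WT past the threshold. In Hepa1-6 tumours Tet2 (3:133126641-133207354) averaged a scaled FPKM of 2.22 ± 0.475 in WT and 3.07 ± 0.248 in KO (n = 4 each, SD; log2 difference 0.35, SE 0.11, limma adjusted p = 0.0518). The means were 4.96 ± 0.335 and 4.53 ± 0.200 in Py8119 tumours, 7.96 ± 4.40 and 8.49 ± 4.76 in tumour-free G-MDSC, and 9.97 ± 2.13 and 10.1 ± 0.877 in tumour-bearing G-MDSC (n = 2 each). Tet3 (6:83312368-83391672) averaged 4.0 ± 0.256 and 3.87 ± 0.17 in Hepa1-6 tumours, and 6.78 ± 0.0403 and 5.61 ± 0.0499 in Py8119 tumours. Its means were 8.68 ± 0.532 and 9.36 ± 1.85 in tumour-free and 9.31 ± 0.670 and 8.44 ± 0.635 in tumour-bearing G-MDSC. Tet1 stayed at or below 0.107 in each group mean. FPKM sum a whole gene, so the loss of a part of the Tet2 transcript would not be seen here, and the injected tumour cells carry their own Tet2.

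Hepa1-6 tumours in KO hosts held more RNA of liver-secreted proteins than those in WT hosts. Apoa1, the main protein of high-density lipoprotein (9:46036713-46038552), averaged 76.1 ± 42.8 in KO and 2.77 ± 1.79 in WT (log2 difference 4.15, SE 0.57, limma adjusted p = 0.00413, n = 4 each). The alpha-1-antitrypsin genes share much of their sequence, so that the split of fragments between them is uncertain. Serpina1b rose by 3.23 (SE 0.59, limma adjusted p = 0.00899) and Serpina1a by 3.06 (SE 0.54, limma adjusted p = 0.00811). Serpina1c rose by 2.94 (SE 0.49, limma adjusted p = 0.00660) and Serpina1d by 2.60 (SE 0.49, limma adjusted p = 0.00944). KO replicate 2 stood apart, with Serpina1b at 2.46 (other KO libraries 27.4 to 28.9) and Serpina1d at 1.01 (others 10.5 to 11). Fabp1, a liver fatty acid carrier (6:71149882-71155017), averaged 10.2 ± 7.59 in KO and 0.186 ± 0.231 in WT (log2 2.78, SE 0.61, limma adjusted p = 0.0150). Ambp (4:62804313-62815176) rose from 23.9 ± 7.73 to 149 ± 41.5 (log2 2.60, SE 0.25, limma adjusted p = 0.00157). Glod5 (X:7581327-7595618) rose from 0.784 ± 0.322 to 11 ± 2.98, with the smallest limma adjusted p of this comparison, 0.000139.

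Of the 19 measured liver-secreted genes, 16 rose and 0 fell (18 and 0 adjusted over the list alone), with a median log2 difference of 1.56. Fgg and Fga, which encode fibrinogen chains, rose from 89.8 ± 24.5 to 314 ± 62.5 and from 44.3 ± 15.8 to 221 ± 64.2, and Ahsg from 52.4 ± 15.2 to 233 ± 70.7. The camera test of the list gave adjusted p = 2.58e-13, and adjusted p = 0.426 with an estimated correlation. Of 22 cholesterol synthesis genes 8 rose and 0 fell (15 and 0 over the list alone; median 0.53; camera adjusted p = 3.64e-05, and adjusted p = 0.525 with an estimated correlation). Tm7sf2 (1.88 to 4.37) and Fdps (3.62 to 7.65) were among them. Of 35 ribosomal protein genes 4 rose and 0 fell (1 and 0 over the list alone; median 0.33; camera adjusted p = 2.15e-05, and adjusted p = 0.525 with an estimated correlation). Rps2 rose from 215 to 356, and Rpl6 from 51.2 to 68.2 with a limma adjusted p of 0.0346. The call of Rpl6 ended without WT replicate 1, 2 or 4 or KO replicate 3 or 4 (limma adjusted p = 0.0848, 0.0616, 0.0582, 0.104 and 0.102). None of 24 proliferation genes passed, 23 of them were higher in KO (median 0.29), and the list gave camera adjusted p = 0.0166, and adjusted p = 0.712 with an estimated correlation.

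Genes of T cells and of cytotoxic lymphocytes were lower in KO hosts. Of 19 T-cell core genes 18 fell and 0 rose (18 and 1 over the list alone), with a median log2 difference of -1.16. Cd6 fell from 25.2 ± 3.68 to 7.48 ± 1.36 and Cd5 from 21.8 ± 4.07 to 7.25 ± 0.488, each with limma adjusted p = 0.00132. Cd2 and Bcl11b fell by 1.19 and 1.02. The camera test gave adjusted p = 1.23e-13, and adjusted p = 0.426 with an estimated correlation. Of 15 cytotoxic effector genes 12 fell and 0 rose (14 and 0 over the list alone; camera adjusted p = 2.02e-09, and adjusted p = 0.426 with an estimated correlation). Ifng, the gene of IFN-γ, fell from 39.8 ± 12 to 9.01 ± 6.02, Ctsw from 31.9 ± 2.36 to 11 ± 3.07 and Cst7 from 68.0 to 22.1. Of 11 checkpoint receptor genes 8 fell and 0 rose (9 and 0 over the list alone; median -1.36; camera adjusted p = 2.10e-06, and adjusted p = 0.426 with an estimated correlation). Havcr2 went from 26.2 to 8.92, Lag3 from 88.3 to 29.3 and Icos from 17.3 to 6.58. Of 6 NK cell genes 3 fell (3 over the list alone; median -0.90; camera adjusted p = 0.0140, and adjusted p = 0.481 with an estimated correlation). Without WT replicate 3 the NK cell list gave camera adjusted p = 0.0546. Il2rb of this list fell by 1.29. Ptprc, the CD45 gene carried by leukocytes, averaged 74.0 ± 15.0 in WT and 42.0 ± 9.91 in KO, and Cd3e of T cells 111 ± 28.6 and 41.5 ± 14.2.

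Interferon response and MHC class I genes were lower in KO hosts too. Of 21 IFN-γ response genes 16 fell and 0 rose (18 and 0 over the list alone; median -0.81; camera adjusted p = 2.98e-10, and adjusted p = 0.481 with an estimated correlation). Cxcl10, a chemokine that draws T cells, fell from 77.5 ± 6.78 to 31.7 ± 10.7, Irf1 fell by 0.79 and Gbp5 by 1.04. Of 15 MHC class I genes 10 fell and 0 rose (13 and 0 over the list alone; median -0.59; camera adjusted p = 6.90e-07, and adjusted p = 0.481 with an estimated correlation). The peptide transporter genes Tap1 and Tap2 fell by 0.62 and 0.92, and Tapbp by 0.86. Of 25 type I interferon-stimulated genes 9 fell and 0 rose (10 and 0 over the list alone; median -0.51; camera adjusted p = 1.58e-06, and adjusted p = 0.525 with an estimated correlation). Xaf1 (6.20 to 4.14) and Ddx58 (9.90 to 6.82) were among them.

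Macrophage and inflammatory genes were lower as well. Of 16 macrophage genes 10 fell and 1 rose (13 and 1 over the list alone; median -1.01; camera adjusted p = 1.46e-05, and adjusted p = 0.507 with an estimated correlation). Trem2 went from 35.7 to 6.07, the complement gene C1qc from 250 to 126, and Folr2 from 14.4 to 1.60. Of 20 inflammatory genes of the NF-kB list 6 fell and 0 rose (9 and 0 over the list alone; camera adjusted p = 7.52e-05, and adjusted p = 0.525 with an estimated correlation). Icam1 fell from 44.6 to 27.5, and Ccl4, whose groups overlapped, from 203 to 47.5. Of 19 immediate-early genes 3 fell (2 over the list alone; median -0.33; camera adjusted p = 0.0167, and adjusted p = 0.712 with an estimated correlation). Their mean log2 level ran from 4.50 to 5.03 over WT libraries and from 4.12 to 4.48 over KO libraries, so that the lowest WT and highest KO library were nearly level. The 21 suppressor-function genes moved both ways, with 8 falling and 4 rising (11 and 4 over the list alone; median -0.73; camera adjusted p = 0.0117, and adjusted p = 0.563 with an estimated correlation). Cd84 fell by 1.57, while the fatty acid transporter Slc27a2, the arginase Arg2 and the prostaglandin synthase Ptges rose by 1.83, 1.20 and 1.21.

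The largest falls of single genes included a cathepsin, chemokines and neutrophil genes. Ctsk, a collagen-degrading cathepsin (3:95303132-95313309), fell from 32.4 ± 22.3 to 1.99 ± 1.01 (log2 -3.31, SE 0.46, limma adjusted p = 0.00428). The T-cell chemokine Ccl5 (11:83339281-83344020) fell from 1183 ± 459 to 193 ± 85.6 (-2.64, SE 0.37), and Ccl9 (11:83386419-83392138) from 121 ± 121 to 14.9 ± 4.48 (-2.50, SE 0.51). The nitric oxide synthase Nos2 (11:78734361-78773626) fell from 50.8 ± 29.9 to 9.52 ± 10.1 (-2.59, SE 0.57). Nos2 gave limma adjusted p = 0.0153, and 0.0561 with the replicate number as a block. Retnlg, expressed in neutrophils (16:48872721-48874611), fell from 362 ± 170 to 64.7 ± 47.9 (-2.63, SE 0.65, limma adjusted p = 0.0210, and 0.0592 with the block). Without KO replicate 1 Retnlg gave limma adjusted p = 0.0555, and without KO replicate 4 0.0663. Mmp25 (17:23766425-23782236) fell by 2.59, AA467197 (2:122463623-122466812) by 2.63 and Ankrd55 (13:113078659-113174210) by 2.49. The lists of mature neutrophils (camera adjusted p = 0.459), secondary granules (0.147, with 3 members rising and 4 falling), monocytes (0.425) and dendritic cells (0.580) did not pass. Nor did those of MHC class II (camera adjusted p = 0.147), granulocyte chemoattractants (0.147), regulatory T cells (0.459), B cells (0.701) and plasma cells (0.823). KO replicate 3 stood apart in several of these, with a mean log2 level of 4.47 over mature neutrophil genes (other KO libraries 2.37 to 2.61, WT mean 3.12 ± 0.589). Over secondary granule genes it stood at 5.74 (others 4.23 to 4.68, WT mean 5.17) and over B-cell genes at 3.81 (others 1.42 to 1.74, WT mean 2.01 ± 0.294). The B-cell list had a positive median (0.54) and mean (0.10) although the direction of its test was down, and without KO replicate 3 19 lists passed instead of 15. The 8 erythroid genes averaged a log2 level of 5.96 ± 0.735 in WT and 7.10 ± 1.10 in KO (median difference 1.33, camera adjusted p = 0.0761, and 0.0127 with the block). The 8 genes of basophils, eosinophils and mast cells averaged 3.26 ± 0.457 and 2.33 ± 0.525, with 4 falling and 1 rising (median difference -1.08, camera adjusted p = 0.0790). Outside immune cells, the lists of hypoxia (0.147), heat shock (0.108), endothelium (0.688), fibroblasts (0.862), keratinocytes (0.459), mammary cells (0.916), oxidative phosphorylation (0.701) and TET and DNMT genes (0.536) did not pass.

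In all, 2378 of 11996 genes changed between Hepa1-6 tumours of KO and WT hosts, 1075 higher and 1303 lower, and 4441 had an unadjusted p under 0.05 (limma). The groups of 3716 genes (31.0%) did not overlap, where chance gives 2.86% for a single gene. Genes share the libraries and are not replicates, so that this share is no test of the difference between groups. With the replicate block 1661 genes passed, and 839 passed without KO replicate 4, 885 without KO replicate 3 and 1325 without KO replicate 1. FPKM as deposited gave 314 higher and 2194 lower with a median shift of -0.16 over all genes. WT replicate 4 and KO replicates 3 and 4 stood apart in interferon, neutrophil, B-cell or red-cell genes, and KO replicate 2 in alpha-1-antitrypsin genes. Without the first 3 of these, a choice made after seeing the data, 101 genes passed.

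**Figure D1:**
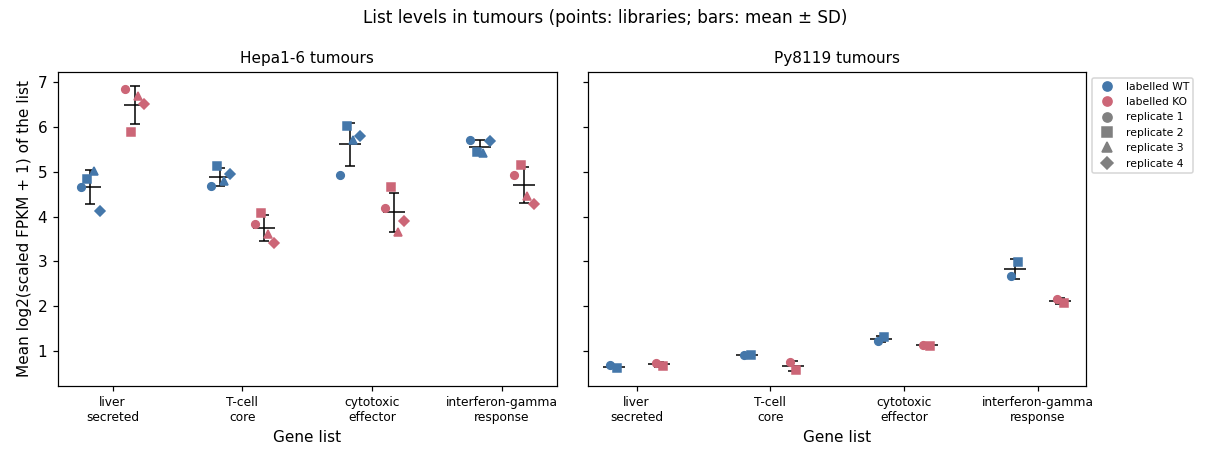
Mean log2(scaled FPKM + 1) of the liver-secreted, T-cell core, cytotoxic effector and IFN-γ response lists in each tumour library, with the mean and SD of each group; Hepa1-6 and Py8119 tumours stand in separate panels.

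Py8119 tumours of KO hosts differed from those of WT hosts in 9 genes, of which 6 are short RNA genes. Rnase4, a secreted ribonuclease (14:51710752-51725826), rose from 14.9 ± 4.70 to 53.8 ± 14.7 (log2 1.79, SE 0.24, limma adjusted p = 0.0155, n = 2 each). Actg2, the smooth muscle gamma actin (6:83462903-83486245), rose from 4.93 ± 0.813 to 11.5 ± 0.915 (1.08, SE 0.13, limma adjusted p = 0.00884). Prl2c2, a hormone gene of the prolactin family (13:13088391-13097597), fell from 22.1 ± 5.30 to 7.85 ± 1.74 (-1.38, SE 0.17, limma adjusted p = 0.00967). With the replicate block the limma adjusted p of these genes were 0.271, 0.169 and 0.260.

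The gene lists of Py8119 tumours shifted without single members passing over all genes. The 21 IFN-γ response genes were lower in KO hosts (median log2 difference -0.73; 11 lower over the list alone; camera adjusted p = 7.69e-16, and adjusted p = 0.463 with an estimated correlation). Gbp4 stood at 0.863 ± 0.136 in KO and 2.63 ± 0.236 in WT, Iigp1 at 2.52 and 10.2, and Cxcl9 at 1.33 and 5.96. The 15 MHC class I genes were lower too (median -0.57; 3 over the list alone; camera adjusted p = 9.98e-09, and adjusted p = 0.463 with an estimated correlation). Tap1 stood at 9.98 ± 0.385 and 18.0 ± 2.08 and Nlrc5 at 3.65 and 6.65. All 16 macrophage genes were higher in KO (median 0.68; camera adjusted p = 9.98e-09, and adjusted p = 0.463 with an estimated correlation). The complement genes C1qa, C1qb and C1qc stood at 518, 496 and 442 ± 55.5 in KO and at 324, 264 and 231 ± 2.37 in WT. Leukocytes' Ptprc averaged 5.81 ± 0.127 in WT and 8.13 ± 0.589 in KO.

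The erythroid list was higher in Py8119 tumours of KO hosts (8 members, median 2.13; camera adjusted p = 2.74e-05, and adjusted p = 0.463 with an estimated correlation). Hba-a1 stood at 341 and 86.6 and Hbb-b1 at 76.3 and 17.2. Granulocyte chemoattractants were higher (median 0.57, camera adjusted p = 0.00355, and adjusted p = 0.518 with an estimated correlation). Csf3 stood at 6.99 and 4.13 and Cxcl1 at 13.3 and 3.12. Mature neutrophil genes (median 0.38, camera adjusted p = 0.00298, and adjusted p = 0.881 with an estimated correlation) included S100a8 at 6.78 ± 5.41 and 0.350 ± 0.0202. Monocyte genes (median 0.21, camera adjusted p = 0.00571, and adjusted p = 0.463 with an estimated correlation) included Ccr2 at 27.8 ± 15.8 and 8.94 ± 1.67. Without KO replicate 1 the chemoattractant, mature neutrophil, monocyte and endothelial lists gave camera adjusted p of 0.648, 0.648, 0.335 and 0.207. Without WT replicate 2 they gave 0.0717, 0.265, 0.359 and 0.760. The endothelial (median 0.27, camera adjusted p = 0.000813, and adjusted p = 0.472 with an estimated correlation) and fibroblast lists (0.19, camera adjusted p = 0.00571, and adjusted p = 0.463 with an estimated correlation) were higher. So were proliferation (0.18, camera adjusted p = 0.0147) and secondary granule genes (0.54, camera adjusted p = 0.0147, and 0.0700 with the block), each with adjusted p = 0.881 with an estimated correlation. The T-cell core list was lower (median -0.08, mean -0.24, camera adjusted p = 0.0188, and adjusted p = 0.881 with an estimated correlation; 0.119 without WT replicate 1). Immediate-early genes were lower too (-0.20, camera adjusted p = 0.0465, and adjusted p = 0.881 with an estimated correlation). The liver-secreted (camera adjusted p = 0.389), cytotoxic (0.334), checkpoint (0.780) and type I interferon-stimulated lists (0.0977) did not pass.

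Of all genes, 5 were higher and 4 lower in Py8119 tumours of KO hosts, and 487 had an unadjusted p under 0.05 (limma). The groups of 3185 genes (26.6%) did not overlap, where chance gives 33.3% for 2 against 2 libraries that are not paired. Leaving out single libraries gave 39 to 54 genes, no filter gave 135, and leaving out short RNA genes gave 3.

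The KO effect differed between the tumour lines in 10 genes (5 each way), of which 6 are short RNA genes, and 2321 genes had an unadjusted p under 0.05 (limma). The KO effect on Glod5 was higher in Hepa1-6 tumours (difference of log2 differences 2.69, SE 0.33, limma adjusted p = 0.00929, and 0.113 with the block). So was that on the carboxylesterase Ces1c (8:95622915-95655182; 2.23, SE 0.26, limma adjusted p = 0.00644, and 0.0493 with the block). The differences of Ms4a6b (19:11593049-11604893) and Actg2 were -2.23 and -1.08 (limma adjusted p = 0.0459 and 0.0446, and 0.145 and 0.143 with the block). Their calls ended without Hepa1-6 KO replicate 1 (limma adjusted p = 0.102 and 0.0849) and without other single libraries. Without Hepa1-6 KO replicate 2, 146 genes passed, among them Ambp, Cd6 and Trem2.

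The lists with which the tumour lines differed were led by liver, T-cell and macrophage genes. The KO effect on the liver-secreted list was higher in Hepa1-6 tumours (median difference 1.53; 15 genes over the list alone; camera adjusted p = 1.08e-09, and adjusted p = 0.609 with an estimated correlation). Ambp and Fgg differed by 2.69 and 1.78 without passing (limma adjusted p = 0.0629 and 0.0999). The T-cell core list (-0.99; 12 genes over the list alone; camera adjusted p = 1.12e-09, and adjusted p = 0.609 with an estimated correlation) had Cd5 at -1.39 and Cd6 at -1.40. The macrophage list (-1.79; 13 genes over the list alone; camera adjusted p = 2.37e-09, and adjusted p = 0.609 with an estimated correlation) had Trem2 at -2.95 and C1qc at -1.92. The cytotoxic (-1.16, 8 genes over the list alone, camera adjusted p = 1.08e-06) and checkpoint lists (-1.21, 5 genes, camera adjusted p = 0.000146) had lower KO effects in Hepa1-6 tumours, each with adjusted p = 0.618 with an estimated correlation. The NF-kB list (-0.58, camera adjusted p = 0.000408), the chemoattractants (-0.91, 0.00443), the suppressor-function genes (0.00675) and the cholesterol synthesis genes (0.51, 0.00369) differed too, with adjusted p = 0.659 with an estimated correlation. Interferon-stimulated genes (-0.36, camera adjusted p = 0.00443, and adjusted p = 0.678 with an estimated correlation) and ribosomal genes (0.31, 0.0167, and adjusted p = 0.713 with an estimated correlation) differed. So did mature neutrophil (-0.45, camera adjusted p = 0.0265, and adjusted p = 0.823 with an estimated correlation) and secondary granule genes (-0.88, 0.0265, and 0.0702 with the block, and adjusted p = 0.659 with an estimated correlation). The monocyte list (-0.83, camera adjusted p = 0.0417, and adjusted p = 0.659 with an estimated correlation) gave 0.123 with the block, and its call ended without Hepa1-6 KO replicate 1 (0.0505). The IFN-γ response (camera adjusted p = 0.326) and MHC class I lists (0.368), lower in KO hosts with either line, were not shown to differ between the lines.

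Of the genes higher in KO hosts, 1 passed in both tumour lines (0.448 expected by independence), and of those lower 0 did (0.434 expected). Over all genes the differences of both lines had the same sign in 45.6%, and in 42.3% of the genes that changed in Hepa1-6 tumours, with a Spearman rho of -0.0983.

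In G-MDSC of tumour-free mice 0 of 9419 genes changed between KO and WT (limma), 103 had an unadjusted p under 0.05, and the smallest limma adjusted p was 0.0728. The genes with the smallest p are named without having passed. Lgals1, which encodes galectin-1, averaged 9.87 in KO and 2.97 in WT (log2 differences 0.81 in the 1st set and 2.26 in the 2nd). Dnajc15 averaged 6.30 and 2.82, Ms4a4b 5.03 and 2.02, Ms4a6c 5.95 and 1.14 and Coro2a 10.7 and 6.60. Cdc42ep2, an effector of the GTPase Cdc42 (19:5917556-5924816), averaged 4.33 ± 1.48 in KO and 28.8 ± 8.40 in WT (log2 -2.48, with -1.90 and -3.06 in the sets). Krt80 averaged 4.48 and 22.1, Dnah8 2.28 and 7.98, Plcb3 3.35 and 8.80 and Acta2 2.75 and 7.77.

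Markers of other cells were higher in the tumour-free KO preparations. The erythroid list had a median log2 difference of 1.69 over 19 members (0.0071 in the 1st set and 3.61 in the 2nd; camera adjusted p = 2.76e-22, and adjusted p = 0.467 with an estimated correlation). Slc4a1, the anion exchanger of red cells, averaged 32.4 ± 31.1 in KO and 5.28 ± 6.27 in WT. T-cell core genes (0.54, with 0.16 and 0.87 in the sets; camera adjusted p = 7.66e-10, and adjusted p = 0.467 with an estimated correlation; 0.0631 without WT replicate 2) included Cd3g at 4.60 and 1.94. B-cell genes (0.63, with 0.52 and 0.71; camera adjusted p = 0.000548, and adjusted p = 0.568 with an estimated correlation; 0.168 without WT replicate 1) included Cd79b at 30.7 ± 4.47 and 14.3 ± 1.33. MHC class II genes (0.71, with 0.54 and 0.87; camera adjusted p = 2.52e-05, and adjusted p = 0.494 with an estimated correlation) included H2-Eb1 at 41.6 and 19.1. Monocyte genes (0.82, camera adjusted p = 8.38e-05, and adjusted p = 0.310 with an estimated correlation) were higher too. So were plasma cell (0.40, camera adjusted p = 0.00950, and adjusted p = 0.494 with an estimated correlation) and stem and progenitor genes (0.26, 0.0254, and adjusted p = 0.467 with an estimated correlation).

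Genes of immature granulocytes stood higher in the tumour-free KO preparations. Primary granule genes, made in promyelocytes, had a median of 0.74 (0.35 and 1.07 in the sets; camera adjusted p = 0.000127, and adjusted p = 0.467 with an estimated correlation; 0.0631 without WT replicate 2). Prtn3 averaged 25.9 ± 29.8 and 3.93 ± 0.733 and Mpo at 13.8 and 1.61. Each of 24 proliferation genes was higher (median 0.55; camera adjusted p = 4.98e-06, and adjusted p = 0.555 with an estimated correlation), with Mcm2 at 4.94 and 2.11. The list turned to -0.45 without WT replicate 2 (camera adjusted p = 0.0478). IFN-γ response genes had a median of 0.79, with 1.56 in the 1st set and -0.24 in the 2nd (camera adjusted p = 1.34e-08, and adjusted p = 0.481 with an estimated correlation; 0.927 without KO replicate 1). Immediate-early genes were lower (-0.16 and -1.28 in the sets; camera adjusted p = 1.22e-05, and adjusted p = 0.494 with an estimated correlation; 0.289 without KO replicate 2). Fos averaged 161 ± 112 and 454 ± 202. Cholesterol synthesis genes (-0.31, camera adjusted p = 8.38e-05, and adjusted p = 0.494 with an estimated correlation; 0.984 without KO replicate 1) and interferon-stimulated genes (-0.24, with 0.11 and -0.49 in the sets; camera adjusted p = 0.010, and adjusted p = 0.568 with an estimated correlation) were lower. Ribosomal (0.15, camera adjusted p = 0.00772, and adjusted p = 0.649 with an estimated correlation) and TET and DNMT genes (0.21, 0.0425, and adjusted p = 0.467 with an estimated correlation) were higher. Mature neutrophil genes (-0.17, camera adjusted p = 0.230), suppressor-function genes (0.870) and MHC class I genes (0.0569) did not pass.

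In G-MDSC of tumour-bearing mice 2 short RNA genes, Mir142b and Mir7060, were higher in KO than in WT (smallest limma adjusted p = 0.0383), and 113 genes had an unadjusted p under 0.05. With the set as a block 1 of the 2 short RNA genes passed. The protein-coding genes with the smallest p, none of which passed, included interferon-induced genes. Ifi27l2a (12:104672083-104681890) averaged 691 ± 120 in KO and 221 ± 47.8 in WT (log2 1.65, with 1.25 and 2.05 in the sets, n = 2 each). The nucleic acid sensor Zbp1 (2:173032114-173044423) averaged 72.5 ± 25.2 and 17.8 ± 6.37 (1.96, with 1.25 and 2.67) and Ifi204 (1:175677425-175697050) 28.0 ± 14.5 and 6.18 ± 2.35 (1.96). Gdpd3 (7:133909928-133919159) averaged 36.9 ± 29.7 and 3.41 ± 0.603 (2.84, with 1.80 and 3.88) and Apol11b (15:77464381-77473716) 18.5 ± 7.48 and 1.16 ± 0.211 (3.12). Cdc42ep2 was again lower in KO, at 5.33 ± 1.70 and 25.4 ± 5.99 (-2.07, with -2.02 and -2.11). Krt80 stood at 5.44 and 18.5, Dnah8 at 1.70 and 6.03, Hunk at 4.22 and 11.8 and Plcb3 at 2.86 and 5.50.

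All 23 type I interferon-stimulated genes were higher in tumour-bearing KO G-MDSC, with a median log2 difference of 0.77 (0.55 and 1.14 in the sets). Adjusted over the list alone 4 of them passed, and camera gave adjusted p = 7.70e-31, and adjusted p = 0.322 with an estimated correlation. Ifit1 averaged 23 ± 3.94 in KO and 9.76 ± 3.49 in WT, Usp18 12.1 ± 0.864 and 6.30 ± 0.796 and Xaf1 6.02 and 2.47. MHC class I genes were higher (median 0.56, with 0.35 and 0.84; 14 of 15 positive; camera adjusted p = 1.04e-10, and adjusted p = 0.491 with an estimated correlation; 0.0726 without KO replicate 2). H2-D1 stood at 1267 ± 246 in KO and 642 in WT and Tap1 at 52.5 ± 17.3 and 30.7 ± 0.868. So were IFN-γ response genes (0.71, with 0.22 and 1.12; camera adjusted p = 1.55e-07, and adjusted p = 0.869 with an estimated correlation; 0.633 without KO replicate 2). Igtp stood at 57.3 and 21.4 and Socs1 at 13.4 and 6.39.

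Red-cell genes were higher and T-cell genes lower in the same KO preparations. All 19 erythroid genes were higher (median 1.78, with 1.93 and 1.56 in the sets; camera adjusted p = 1.18e-27, and adjusted p = 0.483 with an estimated correlation). The carbonic anhydrase Car1 stood at 18.7 ± 5.54 and 2.03 ± 0.188 and Klf1 at 8.04 and 1.26. T-cell core genes were lower (-0.40, with -0.0063 and -0.87; camera adjusted p = 4.37e-07, and adjusted p = 0.869 with an estimated correlation; 0.875 without WT replicate 2). Cd8a stood at 2.19 and 3.81. Ribosomal genes had a median of 0.12 (0.38 and -0.12; camera adjusted p = 0.0219, and adjusted p = 0.967 with an estimated correlation), which turned to -0.34 without WT replicate 1. Mature neutrophil genes (0.13, camera adjusted p = 0.455) and suppressor-function genes (-0.11, 0.958) did not pass. With the set as a block, secondary granule (camera adjusted p = 0.0137), macrophage (0.00397), oxidative phosphorylation (0.0293) and chemoattractant genes (0.0490) passed as well.

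The groups of 20.9% of genes did not overlap in tumour-free and of 17.3% in tumour-bearing G-MDSC, where chance gives 33.3% for libraries that are not paired and less for libraries paired by set, as these are. No gene passed in both, the Spearman rho of the log2 differences was 0.0468, and 49.9% of genes had the same sign. With 2 libraries a group in sets that differ, the simulations recovered 18.2% or 25.8% of changes of 2 on the log2 scale in tumour-free and 16.7% or 51.5% in tumour-bearing G-MDSC, depending on how the noise was drawn.

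**Figure D2:**
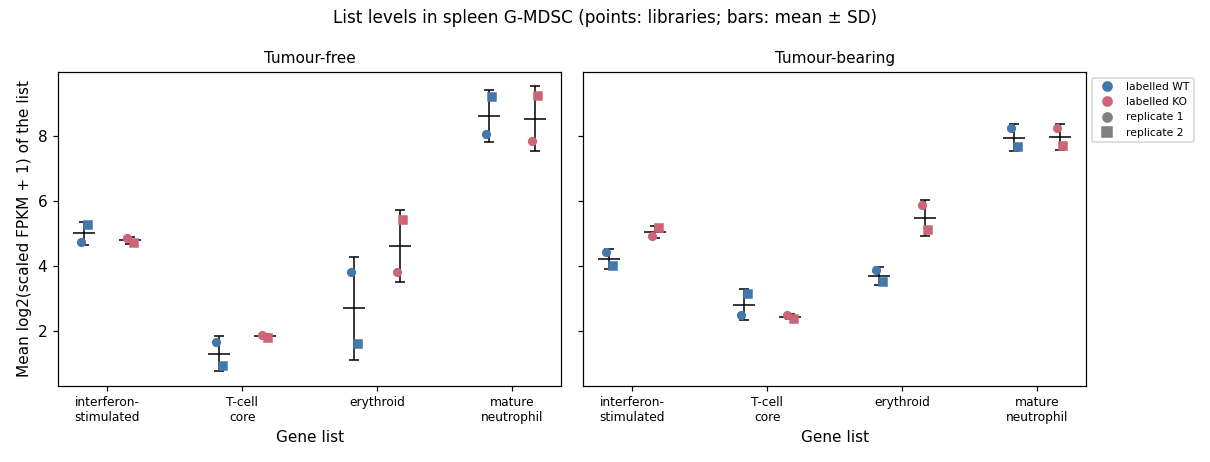
Mean log2(scaled FPKM + 1) of the interferon-stimulated, T-cell core, erythroid and mature neutrophil lists in each G-MDSC library, with the mean and SD of each group; tumour-free and tumour-bearing mice stand in separate panels.

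Between tumour-bearing and tumour-free WT mice 0 genes changed in G-MDSC (limma), and 540 had an unadjusted p under 0.05. T-cell core genes were higher with a tumour (median log2 difference 1.62, with 0.88 and 2.43 in the sets; 15 genes over the list alone; camera adjusted p = 1.40e-21, and adjusted p = 0.425 with an estimated correlation). Lat stood at 10.2 and 1.67 and Cd4 at 4.92 and 0.771. B-cell genes (1.53, with 0.71 and 2.46; camera adjusted p = 1.35e-07, and adjusted p = 0.495 with an estimated correlation) included Cd79b at 65.5 and 14.3. MHC class II genes (1.53, with 0.63 and 2.27; camera adjusted p = 1.17e-08, and adjusted p = 0.425 with an estimated correlation) included H2-Eb1 at 72.9 and 19.1. Plasma cell genes (0.95, camera adjusted p = 1.50e-05, and adjusted p = 0.425 with an estimated correlation) included Igj at 68.4 ± 10.1 and 20.2 ± 3.47. Of the single genes with the smallest p, Ms4a4b stood at 12.8 ± 0.370 and 2.02 ± 0.951, Ms4a6b at 9.78 and 1.77, Slamf6 at 6.79 and 0.791, and Lck and Crip1 were on the same side. Oas1g (3.94 and 14.3), Ifit1 (9.76 and 25.3), Xaf1 (2.47 and 6.69), Usp18 (6.30 and 13) and Stard4 (1.95 and 5.13) were on the other.

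Interferon-stimulated, cholesterol synthesis and granule genes were lower in WT G-MDSC of tumour-bearing mice. The interferon-stimulated list had a median of -0.90 (-0.36 and -1.39 in the sets; camera adjusted p = 1.17e-08, and adjusted p = 0.425 with an estimated correlation). Cholesterol synthesis genes had a median of -0.87 (-0.80 and -1.15; camera adjusted p = 6.45e-09, and adjusted p = 0.425 with an estimated correlation). Secondary granule genes (-1.06, with -0.79 and -1.35; camera adjusted p = 0.00148, and adjusted p = 0.623 with an estimated correlation; 0.0622 without tumour-free replicate 1) included Pglyrp1 at 1281 and 2740. Mature neutrophil genes (-0.73) gave camera adjusted p = 0.0575. Oxidative phosphorylation (-0.32, camera adjusted p = 0.00531, and adjusted p = 0.677 with an estimated correlation) and MHC class I genes (-0.40, 0.0191, and 0.0560 with the block, and adjusted p = 0.653 with an estimated correlation) were lower. Macrophage (1.25, with 0.06 and 2.41; camera adjusted p = 0.000600, and adjusted p = 0.519 with an estimated correlation) and erythroid genes (0.57, with -0.22 and 1.17; 0.000779, and adjusted p = 0.653 with an estimated correlation) were higher. So were monocyte (0.83, camera adjusted p = 0.00163, and adjusted p = 0.425 with an estimated correlation), ribosomal (0.18, 0.00366, and adjusted p = 0.677 with an estimated correlation) and dendritic cell genes (0.65, 0.0365, and 0.0560 with the block, and adjusted p = 0.425 with an estimated correlation).

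Between tumour-bearing and tumour-free KO mice Mir7060 passed (limma adjusted p = 0.0449), and 355 genes had an unadjusted p under 0.05. Without passing, Gdpd3 averaged 36.9 and 3.49, Ifi204 28.0 and 6.10, St3gal6 49.0 and 17.2, Trp53i13 6.16 and 2.34 and Acta2 5.91 and 2.75. On the other side were Nos1ap (2.93 and 6.82), Hipk2 (5.79 and 11.7), Dmwd (3.22 and 9.53), Inpp5j (2.84 and 6.28) and Thap4 (3.99 and 11.6). T-cell core (median 0.71, with 0.66 and 0.72 in the sets; camera adjusted p = 7.98e-08), immediate-early (0.73, with 0.65 and 0.93; 1.05e-05) and erythroid genes (0.87, with 2.1 and -0.36; 7.15e-05) were higher. Without tumour-free replicate 2 the immediate-early list gave camera adjusted p = 0.0636. MHC class II (0.60, with -0.14 and 1.34; camera adjusted p = 0.00331), B-cell (0.58, with -0.11 and 1.35; 0.00883) and plasma cell genes (0.37, 0.0333) were higher, as were ribosomal (0.18, 0.00347) and interferon-stimulated genes (0.14, with 0.07 and 0.50; 0.00347). Cholesterol synthesis (-0.70, with -0.13 and -1.33; camera adjusted p = 7.62e-07), secondary granule (-1.21, with -0.34 and -1.92; 7.38e-05), primary granule (-1.36, with -0.09 and -2.09; 0.00331) and oxidative phosphorylation genes (-0.25, 0.0107) were lower. Without tumour-bearing replicate 2 the granule lists gave camera adjusted p = 0.17 and 0.353. Each of these 12 lists gave adjusted p = 0.751 with an estimated correlation. Fos averaged 512 with and 161 without a tumour, Ltf 2302 ± 2563 and 6138 ± 118 and Elane 1.12 and 15.2. The groups of 37.2% of genes in WT and 30.3% in KO did not overlap, where chance gives 33.3% for libraries that are not paired and less for paired ones.

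The KO effect in G-MDSC passed as different between tumour states for 0 genes (limma, 54 at an unadjusted p under 0.05, smallest adjusted p = 0.388). This fit recovered 0% of simulated changes of up to 2 on the log2 scale, so that it says little on single genes. The interferon-stimulated list had the smallest p of the lists, with KO over WT higher with a tumour than without (median difference 0.35 in the 1st set and 1.67 in the 2nd; camera adjusted p = 2.16e-25, and adjusted p = 0.225 with an estimated correlation). Of its members Ifit1 (1.77), Usp18 (1.45) and Xaf1 (1.29) had the smallest p, without passing. Outside the list, the single genes with the smallest p included Ifi204 (3.13, SE 0.61), Ifi27l2a (2.25), Gdpd3 (3.43) and Gabbr1 (1.35), which did not pass either. T-cell core genes differed the other way (-1.05, with -0.24 and -1.60; camera adjusted p = 2.64e-17, and adjusted p = 0.436 with an estimated correlation), with Lck at -1.43 and Cd8a at -1.15. So did MHC class II (-0.86, with -0.78 and -1.01; camera adjusted p = 8.79e-05, and adjusted p = 0.683 with an estimated correlation) and B-cell genes (-1.0, with -0.89 and -0.95; 0.000230, and adjusted p = 0.683 with an estimated correlation). The last turned to 0.08 without tumour-bearing KO replicate 1 and MHC class II gave 0.899 there. Monocyte (-0.88, camera adjusted p = 0.000521, and adjusted p = 0.225 with an estimated correlation) and macrophage genes (-0.93, 0.0251, and adjusted p = 0.755 with an estimated correlation) were on the same side. So were plasma cell (-0.76, camera adjusted p = 0.000984, and adjusted p = 0.582 with an estimated correlation), primary granule (-0.97, with 0.03 and -2.02; 0.000917, and adjusted p = 0.582 with an estimated correlation) and proliferation genes (-0.56, with 0.32 and -1.40; 0.00200, and adjusted p = 0.784 with an estimated correlation). Immediate-early genes (0.78, with -0.35 and 1.81; camera adjusted p = 0.000145, and adjusted p = 0.683 with an estimated correlation; 0.284 without tumour-free KO replicate 2) were on the other side. So were MHC class I genes (0.32, with -0.34 and 1.08; camera adjusted p = 0.00200, and adjusted p = 0.683 with an estimated correlation) and cholesterol synthesis genes (0.17, 0.0329, and adjusted p = 0.768 with an estimated correlation). Among the genes with the smallest p, Ms4a4b (-1.68), Slamf6 (-1.70), Dhx40 (-2.47), Hunk (-1.54) and Lgals1 (-1.55) were negative.

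Gene bodies of tumour-bearing KO G-MDSC carried more 5mC than those of WT. Of 17790 gene bodies 2272 rose and 9 fell (limma, 5579 at an unadjusted p under 0.05), and the median difference was 2.18 percentage points (3.33 between the samples numbered 1 and 1.09 between those numbered 2). The largest gains were at Ngp, a neutrophil granule gene (9:110322312-110325516), from 21.5% ± 1.80 to 49.0% ± 0.578 (limma adjusted p = 0.000227, n = 2 each), and Hp, the haptoglobin gene (8:112099028-112103072), from 31.1% ± 1.56 to 54.9% ± 2.47. Gper1 (5:139899133-139903754), which overlaps another gene, went from 60.2% ± 3.39 to 84.0% ± 0.919. Eid3 (10:82329371-82330674), which lies within Txnrd1, went from 10.8% ± 4.35 to 34.3% ± 5.17, and Gpr84 (15:103138666-103140869) from 53.6% ± 1.41 to 75.4% ± 1.25. The falls were smaller. Snurf (7:67127387-67150042), which overlaps the imprinted Snrpn, went from 57.5% to 49.0% (limma adjusted p = 0.0445), and Arr3 (X:97800836-97813832) from 73.2% to 66.4% (limma adjusted p = 0.0226). The calls of Slc7a12 (79.7% to 73.9%), Ankrd7 (79.9% to 74.4%) and Trhr (74.0% to 68.8%) ended with the replicate block (limma adjusted p = 0.0618, 0.0763 and 0.0913), and the calls of Snurf and Arr3 without KO replicate 2 (limma adjusted p = 0.163 and 0.0763).

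Neutrophil genes and MHC class II genes were among those with the largest gains of 5mC. Of 16 mature neutrophil gene bodies 11 rose and 0 fell (15 over the list alone), with a median gain of 6.51 points (6.67 and 6.69 by replicate number). Cxcr2, the receptor that guides neutrophils out of the marrow, went from 32% ± 6.95 to 48.1% ± 4.60, and Mmp8 from 48.9% to 60.3%. Of 21 suppressor-function gene bodies 10 rose (16 over the list alone; median 5.00, with 6.17 and 3.83), among them Cd274, the PD-L1 gene, from 49.3% to 59%. The primary granule list, which holds Clec12a (48.9% to 68.6%) besides granule genes, had a median of 7.46 (4 of 5 rising). Secondary granule genes had a median of 4.70 (4 of 11 rising, with Ltf going from 67.7% to 80.2%) and basophil, eosinophil and mast cell genes one of 5.91 (4 of 9). Of 11 MHC class II genes 5 rose (6 over the list alone; median 6.63, with 7.71 and 3.28). The medians were 4.47 for NF-kB (7 of 20), 4.62 for adipocyte (4 of 11) and 3.85 for hypoxia genes (5 of 22). They were 3.78 for B-cell genes (3 of 15), 3.50 for erythroid genes (3 of 12), 3.19 for T-cell genes (5 of 19), 1.55 for interferon-stimulated genes (1 of 24), 1.49 for ribosomal and 1.14 for liver-secreted genes, and no list had a member that fell. In the RNA of such KO preparations the erythroid list was higher by a median of 1.78 on the log2 scale.

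The gain reached gene bodies of each WT level. By WT level, 105 of 1130 gene bodies below 20% rose, 287 of 1530 from 20% to 40%, 771 of 3514 from 40% to 60%, 1069 of 9167 from 60% to 80% and 40 of 2449 above 80%. Over 5 equal groups of genes from low to high expression in these cells the median 5mC in WT was 66.5%, 65.2%, 64.1%, 62.9% and 56.5%, and the median gain was 2.27, 2.38, 2.69, 3.0 and 3.87 points. Both KO samples lay above both WT samples at 10443 gene bodies (58.7%), where chance gives 16.7% for a single gene body and samples that are not paired. Gene bodies share the 4 samples and are not replicates, so an offset of a sample moves many of them together. The share is therefore no test of the difference between groups. Gene bodies away from gene ends gave exact permutation p = 0.333 between samples, the smallest possible. The limma count was 349 without KO replicate 1, 663 without WT replicate 1, 874 without KO replicate 2 and 908 with at least 5 cytosines a region.

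**Figure D3:**
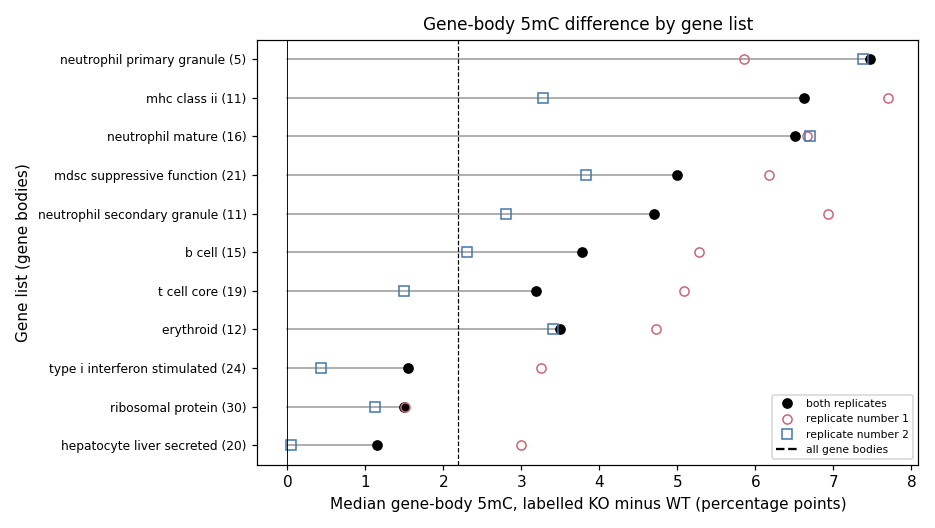
Median difference of gene-body 5mC between KO and WT G-MDSC of tumour-bearing mice for gene lists, over both replicates (filled) and within each replicate number (open); the dashed line marks the median of all gene bodies.

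Genome-wide mean 5hmC was 5.20% ± 0.166 in WT and 4.65% ± 0.947 in KO (difference -0.542, with -1.33 and 0.246 by replicate number; exact permutation p = 1, n = 2 each). The 5hmC level was lower at cytosines of higher coverage, as in WT replicate 1 with 6.78% at a coverage of 20 to 23 and 5.26% at 56 to 59 (autosomal cytosines with 70% to 90% of 5mC and 5hmC together). A line through such values against the inverse square root of coverage reached 2.88% and 2.31% in WT and 1.72% and 2.28% in KO at infinite coverage, so that the absolute level of 5hmC is uncertain. Mean 5mC was 67.6% ± 6.99 and 71.4% ± 2.01 (3.80, with 7.33 and 0.28; exact permutation p = 0.667). Over the cytosines common to all samples 5mC was 70.0% ± 0.941 and 71.7% ± 0.953 (1.71, with 3.05 and 0.375; exact permutation p = 0.333, the smallest possible) and 5hmC differed by -0.556 (-1.48 and 0.364; exact permutation p = 0.667). Gene bodies away from gene ends went from 74.3% ± 0.875 to 76.7% ± 1.07 (2.38, with 3.75 and 1.01; exact permutation p = 0.333), and intergenic cytosines from 73.2% ± 1.03 to 74.4% ± 0.989 (1.26, with 2.69 and -0.166; exact permutation p = 0.667).

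No gene body changed in 5hmC (0 with limma, 1169 at an unadjusted p under 0.05), and the median difference was -0.633 points (-1.40 and 0.151 by replicate number). The smallest p for higher 5hmC in KO, none past the threshold, were at Omt2a (1.40% to 6.80%), Lrrc4 (1.15% to 5.20%), which overlaps Snd1, and Magt1 (2.41% to 8.18%). For lower 5hmC they were at Gjb2 (9.15% to 1.30%), Tlcd1 (6.83% to 0.833%) and Mup13 (7.45% to 0.850%), each with limma adjusted p = 0.10, and with 0.0524, 0.0400 and 0.0390 under the replicate block.

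At gene ends, 1 of 10476 rose in 5mC (limma, 1218 at an unadjusted p under 0.05). That of Fam170a (18:50441673-50443673) went from 29.9% ± 1.11 to 79.5% ± 1.46 (limma adjusted p = 0.0246, and 0.424 with the block; 0.590 without WT replicate 1). In 5hmC 0 gene ends changed (350 at an unadjusted p under 0.05, smallest limma adjusted p = 0.989). Dusp27 (8.31% to 0.885%), Cldn11 and Elovl3 had the smallest p for lower and Zfp526, Mcu and Rufy3 for higher 5hmC. Mean 5mC over gene ends was 28.4% ± 0.650 in WT and higher in KO by 2.15 between the samples numbered 1 and by 1.0 between those numbered 2.

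In tumour-bearing WT G-MDSC gene-body 5hmC correlated with log2 FPKM at a Spearman rho of 0.0929, and its change in KO at -0.0731. The change of gene-body 5hmC correlated with the log2 difference of expression at 0.0357 over 8406 genes, and that of gene-end 5mC at -0.0436 over 5997 genes.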

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

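Of the tests in this part, the 2 that compare the real grouping of the Hepa1-6 libraries with other splits were written in advance, and all others were chosen after the results had been seen. In each tested group of 4 Hepa1-6 libraries, a sample was singled out when its gap to the nearest of the others exceeded Dixon's limit at 95%. Chance does this in about 1 of 20 groups, and 138 groups were tested. They covered a part of the described lists and genes and left out the mature neutrophil, B-cell and immediate-early lists, among others. KO replicate 3 stood apart in the mature neutrophil and B-cell lists, as given above, so that the samples named here are not a full list. WT replicate 4 had a mean log2 level of 4.17 over the type I interferon-stimulated list, with the others at 3.43 to 3.46. KO replicate 3 had S100a8 at a scaled FPKM of 781 (others 43.8 to 84.1) and KO replicate 4 had Hbb-b1 of red cells at 3820 (others 343 to 907). KO replicate 2 stood apart with Serpina1b at 2.46 (others 27.4 to 28.9), Serpina1d at 1.01 (others 10.5 to 11) and Ccl9 at 21.6 (others 12.2 to 13.1). It also did with Havcr2 at 15.4 (others 6.24 to 7.77) and Icos at 9.37 (others 5.51 to 5.90). WT replicate 1 did with Rpl6 at 46.5 (others 52.5 to 53.3) and Ifng at 21.9 (others 44.6 to 47.0), and WT replicate 4 with Slc27a2 at 0.307 (others 0.887 to 0.960). A test of the difference itself singled out the KO effect between the tumour lines, in 10 genes and 14 lists, and between tumour-bearing and tumour-free G-MDSC, in 12 lists.

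The liver-secreted genes were higher and the lymphocyte genes lower in Hepa1-6 tumours of KO hosts. Of the 35 splits of the 8 libraries into 4 and 4, 1 gave as many genes past the threshold, the real one with 2378, and the highest other gave 5. That is a share of 2.86%, the smallest that 35 splits can give, so that chance is unlikely but not excluded for the count of genes. The splits do not separate the genotype from another difference that follows the labels. For the count of lists chance cannot be excluded, since 20 of 35 splits gave at least the real 15 and the highest other gave 25. A smaller share of immune cells alone could raise all tumour-cell genes, but by the same factor, and Cochran's Q of 216 over the 19 liver-secreted members, from H19 at 0.09 to Apoa1 at 4.15, gave 7.16e-36 as the probability of equal change, so that dilution alone does not account for the list. The host genotype is a candidate explanation, as are liver tissue in the samples, tumour size and differences between animals or cages, none of which was tested, and a part of the fall of lymphocyte genes could still be a smaller share of such cells, as Ptprc fell from 74.0 ± 15.0 to 42.0 ± 9.91.

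Gene-body 5mC was higher in tumour-bearing G-MDSC of KO mice. Coverage could cause this. Its mean differed by 17.0 between the samples numbered 1 and by -3.47 between those numbered 2. The median gain was at least 1.09 points in both. At a coverage of 25 to 30 in all samples, gene bodies away from their ends gave 3.20 and 0.378, and all cytosines 2.58 and -0.257. The gain in replicate 1 remained, but coverage could account for that in replicate 2. The sex of the animals could, but the autosomal gain was 3.34 and 1.13 points within the replicate numbers, each of which held samples of 1 sex. DNA of lymphocytes in the KO preparations could, but T-cell and B-cell gene bodies, expected to gain less in that case, lay at percentile 97.0 of the gains of random lists of the same WT level (34 gene bodies). Taken apart, the T-cell list lay at percentile 92.0 and the B-cell list at 96.9. Neither gained less than its random lists, but the T-cell list alone did not reach the 95th percentile, so that lymphocyte DNA is not excluded. The test does not cover DNA of other cells. The genotype, a shift in granulocyte maturity or DNA of nucleated red-cell precursors remains a candidate explanation. Precursor RNA markers were higher in KO by a median of 1.78, but their gene bodies (percentile 92.7) gained no less than such random lists. None was separated here from differences between 2 preparations a group.

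Interferon-stimulated genes were higher in tumour-bearing G-MDSC of KO mice. RNA of other cells in the WT libraries could dilute neutrophil RNA and lower such genes, but the mature neutrophil list differed by a median of 0.13 (spread between members 0.54), against 0.77 for the interferon-stimulated list. A difference between the sets could, but the list was higher in KO in both, by at least 0.55. The genotype remains a candidate explanation, while an unequal interferon exposure of single animals, which no measurement here tests, might look the same with 2 libraries a group.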

How the results depend on the processing

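Counts and levels stayed within 1.5 times their value or 1 SD in 237 of 340 alternatives over 28 results, and 103 moved. Single genes and regions kept their direction and side of the threshold in 3234 of 3387 (247 results), with 108 weaker, 43 stronger and 2 moved, and gene lists in 701 of 820 (59 results), with 114 weaker and 5 reversed. Where leaving out a library leaves 1 sample in a group, the fit assumes that it varies like the other groups. Coverage minimums of 3 and 10 changed no value, since the deposited coverage starts at 20, and each setting chosen in advance was run. The depth of the RNA libraries is unknown, so its limit could not be given. For the changes below the cause was not tested, except where fewer samples or genes were used.

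The Py8119 comparison gave 135 genes with no filter, and 3 without short RNA genes. The difference between tumour lines gave 78 genes with no filter, 306 (and 7 lists) with FPKM as deposited and 2 without short RNA genes. The overlap of the tumour lines was 3 with no filter, and 0 with FPKM as deposited, quantile normalization or the replicate block. Each of the 8 counts of lists was 0 with an estimated correlation (camera). The Hepa1-6 comparison gave 101 genes without WT replicate 4 and KO replicates 3 and 4, and of its 51 named genes 39 lost their call and 12 kept it. This setting was chosen after seeing the data, as were the settings without short RNA, autosomes alone and a coverage minimum of 30.

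Tumour-free G-MDSC gave 1 gene with a pseudocount of 0.1 and 1 with a robust fit, and its overlap with tumour-bearing G-MDSC was 1 with a pseudocount of 0.1. Tumour-bearing G-MDSC gave 1 gene with a pseudocount of 0.1, quantile normalization or the replicate block, and 0 with no filter, with the filter at 5, without short RNA and with the 2 groups alone, and its lists were 10 with the block. The KO tumour effect gave 0 genes with a pseudocount of 0.1, no filter, the filter at 5, FPKM as deposited, no short RNA and the 2 groups alone. Gene-body 5hmC gave 5 regions with the replicate block and 3 on autosomes, gene-body 5mC gave 908 with at least 5 cytosines, and gene-end 5mC gave 0 with the block, with at least 5 cytosines, with 500 bases and with a coverage minimum of 30. The rho of the gene-body 5hmC change with log2 FPKM was -0.0718 with FPKM as deposited, and that of the gene-end 5mC change with the log2 difference -0.0141 with a coverage minimum of 30.

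Leaving out 1 library at a time gave 839 to 2686 genes and 14 to 19 lists in Hepa1-6 tumours, 39 to 54 and 7 to 14 in Py8119 tumours, and 8 to 146 and 6 to 18 for the difference of the lines. In G-MDSC it gave 0 to 9 genes and 12 to 14 lists in tumour-free mice, 4 to 10 and 11 to 14 in tumour-bearing mice, and 2 to 10 and 10 to 15 for the WT tumour effect. The KO tumour effect gave 0 to 9 and 8 to 15, and the difference of the states 0 to 9 and 8 to 15. It gave differences of -1.21 to 0.128 in genome-wide 5hmC and of -1.14 to 8.75 in 5mC, 0 to 27 gene bodies in 5hmC and 349 to 1605 in 5mC, and 0 to 0 gene ends in either. The rho ranged from 0.0712 to 0.0929, -0.0742 to -0.0554, 0.00872 to 0.0555 and -0.0576 to -0.0345. By the direction of the camera test, which can differ from the sign of the median printed here, the reversed lists were the proliferation list of tumour-free G-MDSC (-0.45 without WT replicate 2), the ribosomal list of tumour-bearing G-MDSC (-0.34 without WT replicate 1 and -0.06 without KO replicate 2, over a range of -0.34 to 0.60) and the B-cell list of the difference of the states (0.0795 without tumour-bearing KO replicate 1 and -0.05 without tumour-bearing WT replicate 2, over a range of -2.01 to 0.0795).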

Other observations

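Red-cell, lymphocyte and neutrophil transcripts show how mixed the G-MDSC preparations were. Hbb-b1 averaged 616 ± 831 in WT and 1445 ± 218 in KO preparations of tumour-free mice and 1224 ± 1011 and 3751 ± 3194 in those of tumour-bearing mice (n = 2 each). Cd3e of T cells averaged 1.16 and 2.08 in tumour-free, and 7.87 ± 5.09 and 4.42 ± 0.105 in tumour-bearing mice. S100a8, a calcium-binding protein of neutrophils, averaged 85737 and 75758 in tumour-free, and 40581 and 44730 in tumour-bearing mice.

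Transcripts and cytosines of the sex chromosomes differed between samples. In the DNA samples numbered 1 the median 5mC of 117 gene ends on the X chromosome was 0.667% in WT and 0.929% in KO with 391 and 387 Y cytosines per 1e6, and in those numbered 2 it was 25.2% and 24.4% with 98.6 and 153. Xist, which is expressed from the inactive X of females, averaged 6.70 and 10.4 in Hepa1-6 tumours of WT and KO hosts and 0.0250 and 0.0162 in Py8119 tumours, where Ddx3y of the Y chromosome averaged 1.15 and 1.45, and host RNA was not separated from that of the injected cells. In G-MDSC RNA each group averaged between 10.4 and 18.1 for Xist and at most 0.0030 for Ddx3y. The DNA samples numbered 1 and the Py8119 tumours thus looked male and the other RNA groups female. The labels do not tie DNA to RNA numbers.

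The 3 hypotheses tested next were chosen after the results had been seen. Neutrophil and suppressor-function gene bodies gained more 5mC than others of the same WT level, with a median of 5.64 over 52 gene bodies against a median of 2.33 and a 95th percentile of 3.06 over 10000 random lists (percentile 100). This was not particular to them, since MHC class II (percentile 99.9), NF-kB (99.9), basophil, eosinophil and mast cell (99.5), dendritic cell (98.9), adipocyte (98.9), hypoxia (98.7) and B-cell gene bodies (96.9) also lay above the 95th percentile of their random lists. The hypothesis that 5mC was gained where WT cells hold 5hmC was weighed across replicates, and the rho of WT 5hmC in replicate 1 with the gain in replicate 2 was 0.0700, below the 0.1 set for it, while the other way gave 0.252. Within a replicate the rho were 0.438 and 0.256, which noise of a shared sample could raise. Interferon-stimulated genes had a median of -0.51 in Hepa1-6 tumours and of 0.77 in tumour-bearing G-MDSC of KO mice, and whether these differ is open, since the list passed with an estimated correlation in neither.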
